A study of Mus musculus with 8 samples.

How the data were processed

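RNA was sequenced from 8 samples of B16-OVA cells, 4 Control and 4 HMF. Per the labels' protocols, total RNA was extracted with Trizol, polyadenylated RNA was captured and libraries were built with TIANSeq kits. The deposited table holds read counts per gene, not normalized, and FPKM values for the same 8 libraries. Per the submitters' processing notes, the tools were Trimmomatic, HISAT2 2.0.5, HTSeq and DESeq2 and the genome build was mm10. The role of each tool, the other versions, the gene annotation and the strand setting are not given in the sources used here. The table's gene positions are not those of the mm10 annotation: of 52083 gene identifiers shared with a GRCm38 annotation, 1498 (2.88%) had the same start, and the table contains 2 scaffolds that exist only in GRCm39. The build of the positions was therefore left open and no coordinates are printed. The table has 57353 rows, of which 53924 carry a gene symbol and 1937 are assembled loci without one. These loci took at most 1.36% of the counts of a library, were kept in the tests, and are not named in the text. The deposited FPKM values equal the count divided by the library total and by a single effective gene length that was the same in all libraries.

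Samples were assigned to groups by their titles. Library sizes were scaled with the TMM method, genes were kept by edgeR's filterByExpr with its default settings, and 15082 genes were tested with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with group as the only term. P-values were adjusted by Benjamini-Hochberg, and a gene was called changed at an adjusted p below 0.05. Expression is given as TMM-scaled CPM, the count relative to the scaled library size, mean ± SD over 4 libraries, and fold changes as log2 with their standard errors, which were taken as the absolute log2 fold change over the square root of the quasi-likelihood F statistic. Lists of genes were fixed before the data were examined: 34 lists, of which 32 had at least 3 tested genes and entered the set test. They cover lysosome, autophagy, oxidative phosphorylation, mitochondrially encoded genes, apoptosis, p53, pyroptosis and necroptosis, ferroptosis, NRF2, metals, heat shock, the integrated stress and unfolded protein responses, immediate early genes, YAP-TAZ and SRF, mechanosensitive channels and focal adhesion, calcium, NF-kB and cytokines, type I interferon, MHC class I, danger signals and checkpoints, cGAS-STING, pigmentation, S phase, G2 and mitosis, glycolysis and hypoxia, cholesterol, extracellular matrix, ribosomal proteins, ribosome biogenesis, and markers of macrophages, T and NK cells, fibroblasts and keratinocytes. Symbols were matched to the table directly or through older names, and all were found. The set test was camera (limma 3.58.1) with a preset correlation of 0.01, adjusted over the lists, beside camera with an estimated correlation and fry. Adjustment over the list alone means Benjamini-Hochberg over the tested members of that list.

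Genes named in the text followed a rule fixed before the data were examined. It took the 8 largest rises and the 8 largest falls among changed genes with a mean log2 CPM of at least 1, separated groups and a symbol that is not provisional. It added the 3 members of each list with the smallest adjusted p below 0.05, and a preset group (Piezo1, Hmgb1, Calr, Gsdmd, Gsdme, Hmox1, Hspa1a, Ctsb, Lamp1, Cd274, H2-K1, Mitf, Tyr, Cdkn1a and Atf3). Some genes that the rule takes are not reported here. Total counts were 13973961 to 19295358 per library. Counts were simulated for the 15082 genes of the HMF and Control comparison, with 200 genes changed singly and a further list raised 2-fold. Of the genes changed singly, the test recovered 58.5% of those changed 1.5-fold, 82.5% of those changed 2-fold and 98.5% of those changed 4-fold. Of 180 calls 10 were false. No pair of libraries differed by as little as sampling noise: the lowest chi-square per degree of freedom within a group was 2.13.

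The alternatives were other scalings (RLE size factors, upper quartile, library size alone), no count filter or a CPM of at least 1 in 4 libraries, the replicate number as a block, leaving out each library, DESeq2 1.42.0, limma-voom, limma on log2 FPKM with pseudocounts of 1 and 0.1, an adjusted p below 0.01, edgeR's glmTreat against a 2-fold change, and the set tests above. A covariate, the mean log2 CPM of the glycolysis and hypoxia list, was added after the data were seen. A spread test for groups of 4 (Dixon, critical value 0.829) was applied to the named genes, list means and library measures. GC content came from transcripts of the GRCm38 annotation, matched by gene identifier for 14031 of 15082 tested genes (93.0%). Pathway names deposited with the table were tested after the data were seen, for pathways of 10 to 300 tested genes. Python 3.11.15 with matplotlib 3.10.9 drew the figures.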

Results

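Gene expression was measured by RNA sequencing in B16-OVA cells, a mouse melanoma line derived from B16F10 that expresses the model antigen ovalbumin. The 8 libraries fell into 2 groups of 4. Control libraries came from untreated cells, and HMF libraries came from cells that were incubated for 24 h with rod-shaped magnetic micromotors and then exposed to a high-frequency magnetic field. Cells were collected 6 h after the treatment. The groups were read from the sample titles, because the treatment tag of the labels is the same for all 8 libraries. Both parts of the treatment were applied together in every HMF library, so each value below belongs to the combination of micromotors and field. The total count per library ranged from 13973961 to 19295358, with 16055655 ± 1517797 in Control and 15790940 ± 2360315 in HMF (SD, n = 4 each). Mitochondrially encoded genes took 3.70% ± 0.580 of the counts in Control and 3.32% ± 0.885 in HMF (SD, n = 4; exact permutation test, two-sided, p = 0.514, 0.771 after adjustment over 3 library measures). The share of 18S ribosomal RNA was 0.734% ± 0.194 in Control and 0.561% ± 0.114 in HMF (SD, n = 4; exact permutation test, two-sided, p = 0.2, adjusted 0.6). Pearson correlations of log2 CPM across genes were 0.983 to 0.993 between libraries of the same group and 0.959 to 0.976 between groups. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

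The comparison of HMF with Control asks which transcripts differed after the treatment, in a study of how a mechanical stimulus inside tumour cells leads to their death. Among genes with a mean log2 CPM of at least 1 and an established symbol, the highest rises were in interferon-induced genes and chemokines. Ifi213, a member of the interferon-inducible Ifi200 family, went from 0.293 ± 0.0774 to 14.8 ± 1.90 CPM (SD, n = 4), a log2 fold change of 5.63 ± 0.20 (SE, adjusted p = 1.42e-08). Gbp10, a guanylate-binding protein gene, rose by 5.63 ± 0.20 (adjusted p = 1.5e-08) and Oas3, an antiviral oligoadenylate synthetase gene, by 5.14 ± 0.30 (adjusted p = 5.33e-07). The chemokine genes Cxcl11 and Cxcl9 rose by 5.49 ± 0.65 and 4.83 ± 0.42, and the product of Cxcl9 attracts activated T cells. The serpin gene Serpina3f rose by 5.05 ± 0.48, the nucleic acid sensor gene Zbp1 by 4.91 ± 0.14 and Ifi209 by 4.86 ± 0.42. Without HMF 4 the rise of Cxcl11 was 4.78, and without Control 1 that of Ifi209 was 5.53.

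The largest falls were smaller. Ankle1, a nuclease gene, fell by 2.46 ± 0.19 on the log2 scale, from 46.8 ± 10.5 to 8.45 ± 1.98 CPM (SD, n = 4; adjusted p = 5.06e-06). The DNA helicase gene Pif1 fell by 2.04 ± 0.18, the mitotic regulator gene Pimreg fell by 1.93 ± 0.17, the spindle motor gene Kif11 by 1.90 ± 0.17, Arhgef39 by 1.90 ± 0.21 and the kinetochore gene Cenpf by 1.89 ± 0.17. Hs3st1, a heparan sulfate sulfotransferase gene, fell by 2.10 ± 0.29 and Kank4 fell by 2.07 ± 0.22. Of 15082 genes tested, 4030 changed at an adjusted p below 0.05, of which 2073 rose and 1957 fell (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, n = 4 per group). The share of rises, 51.4%, depended on the scaling. With library sizes alone in place of TMM it was 41.7% (1743 rises and 2435 falls). The deposited FPKM values are likewise scaled by library total alone. On them, with a pseudocount of 1, limma called 1625 rises and 2311 falls (41.3%). At least 2-fold changes numbered 843, with 507 rises and 336 falls. All 4 HMF libraries lay on the same side of all 4 Control libraries for 4387 of the tested genes (29.1%, where chance alone separates 2.86%), 3638 of them changed.

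**Figure D1:**
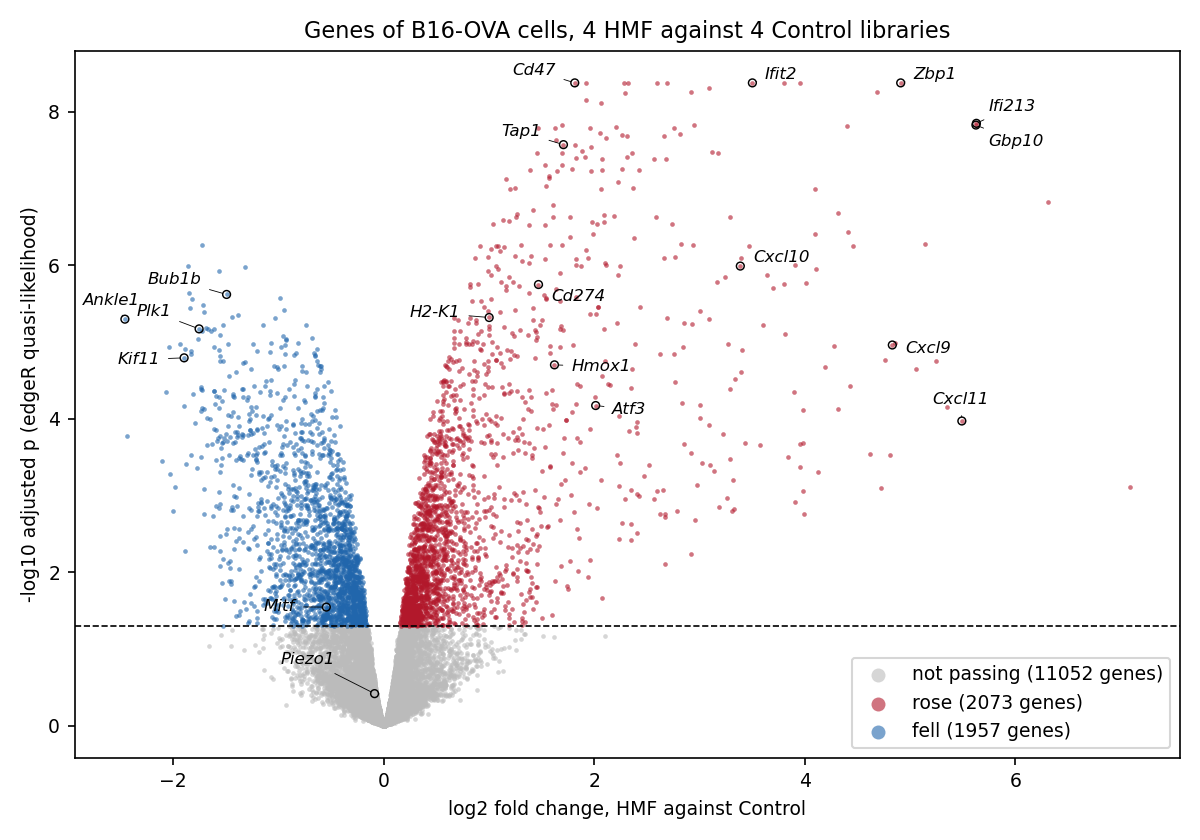
Each point is a gene, with its log2 fold change (HMF against Control) on the horizontal axis and the -log10 of its adjusted p on the vertical axis; the dashed line marks an adjusted p of 0.05. Rises extended further than falls: Ifi213 stood at 5.63 and Ankle1 at -2.46.

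Genes of the type I interferon response rose together. All 28 tested members rose (28 adjusted over the list alone), with a median log2 fold change of 1.94 (camera adjusted p = 7.19e-121, 0.00652 with an estimated correlation). Ifit2, whose product binds viral RNA, rose from 95.3 ± 3.87 to 1080 ± 148 CPM (SD, n = 4), a log2 fold change of 3.50 ± 0.10 (adjusted p = 4.24e-09). Ifi44 rose by 2.69 ± 0.08 and Ifit3b by 2.28 ± 0.07. Of 11 tested genes of the cGAS-STING pathway, which senses DNA in the cytosol, 8 rose and none fell (8 and none adjusted over the list alone; median 0.32, camera adjusted p = 3.88e-11, 0.00652 with an estimated correlation). The members with the smallest p were Samhd1 (1.92 ± 0.06), Ifi204 (2.66 ± 0.10) and Ifi203 (1.53 ± 0.08), which are themselves interferon-inducible. The sensor gene Cgas (log2 fold change -0.17), Irf3 (0.05) and Mavs (-0.07) did not pass, and Tmem173, which encodes STING, rose by 0.18.

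Antigen presentation genes rose as well. In the MHC class I list 17 of 19 tested genes rose and none fell (17 adjusted over the list alone; median 1.69, camera adjusted p = 6.9e-53, 0.00652 with an estimated correlation). The peptide transporter genes Tap2 and Tap1 rose by 2.05 ± 0.08 and 1.71 ± 0.07, and Nlrc5, a transcriptional activator of MHC class I genes, by 1.81 ± 0.07. H2-K1, a classical MHC class I heavy chain gene, went from 709 ± 48.1 to 1420 ± 117 CPM (SD, n = 4), a log2 fold change of 1.001 ± 0.08 (adjusted p = 4.82e-06). The endoplasmic reticulum chaperone genes Calr (-0.12, adjusted p = 0.254) and Pdia3 (0.02) did not pass. Among 14 tested danger signal and immune checkpoint genes, 7 rose and 1 fell (7 and 1 adjusted over the list alone; median 0.44, camera adjusted p = 1.8e-08, 0.0256 with an estimated correlation). Cd47, which encodes a signal against phagocytosis, rose by 1.81 ± 0.05, Lgals9 by 1.16 ± 0.05 and Cd274, which encodes the checkpoint ligand PD-L1, by 1.47 ± 0.10. Hmgb1, which encodes a nuclear protein that acts as a danger signal outside the cell, fell by 0.33 ± 0.08 (adjusted p = 0.00846).

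All 19 tested genes of the NF-kB and inflammatory cytokine list rose (19 adjusted over the list alone). Their median was 1.73 (camera adjusted p = 2.19e-21, but adjusted p = 0.155 with an estimated correlation). Cxcl10 went from 183 ± 40.7 to 1909 ± 585 CPM (SD, n = 4), a log2 fold change of 3.39 ± 0.22 (adjusted p = 1.03e-06). Ccl5, another T cell chemokine gene, rose by 2.77 ± 0.17, and Csf1, which encodes a macrophage growth factor, by 1.53 ± 0.11. Of 21 tested immediate early genes, 11 rose and none fell (11 adjusted over the list alone; median 0.60, camera adjusted p = 1.6e-05, adjusted p = 0.245 with an estimated correlation). Atf3 rose by 2.01 ± 0.22, Zfp36 by 1.68 ± 0.14 and Junb by 1.46 ± 0.12.

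**Figure D2:**
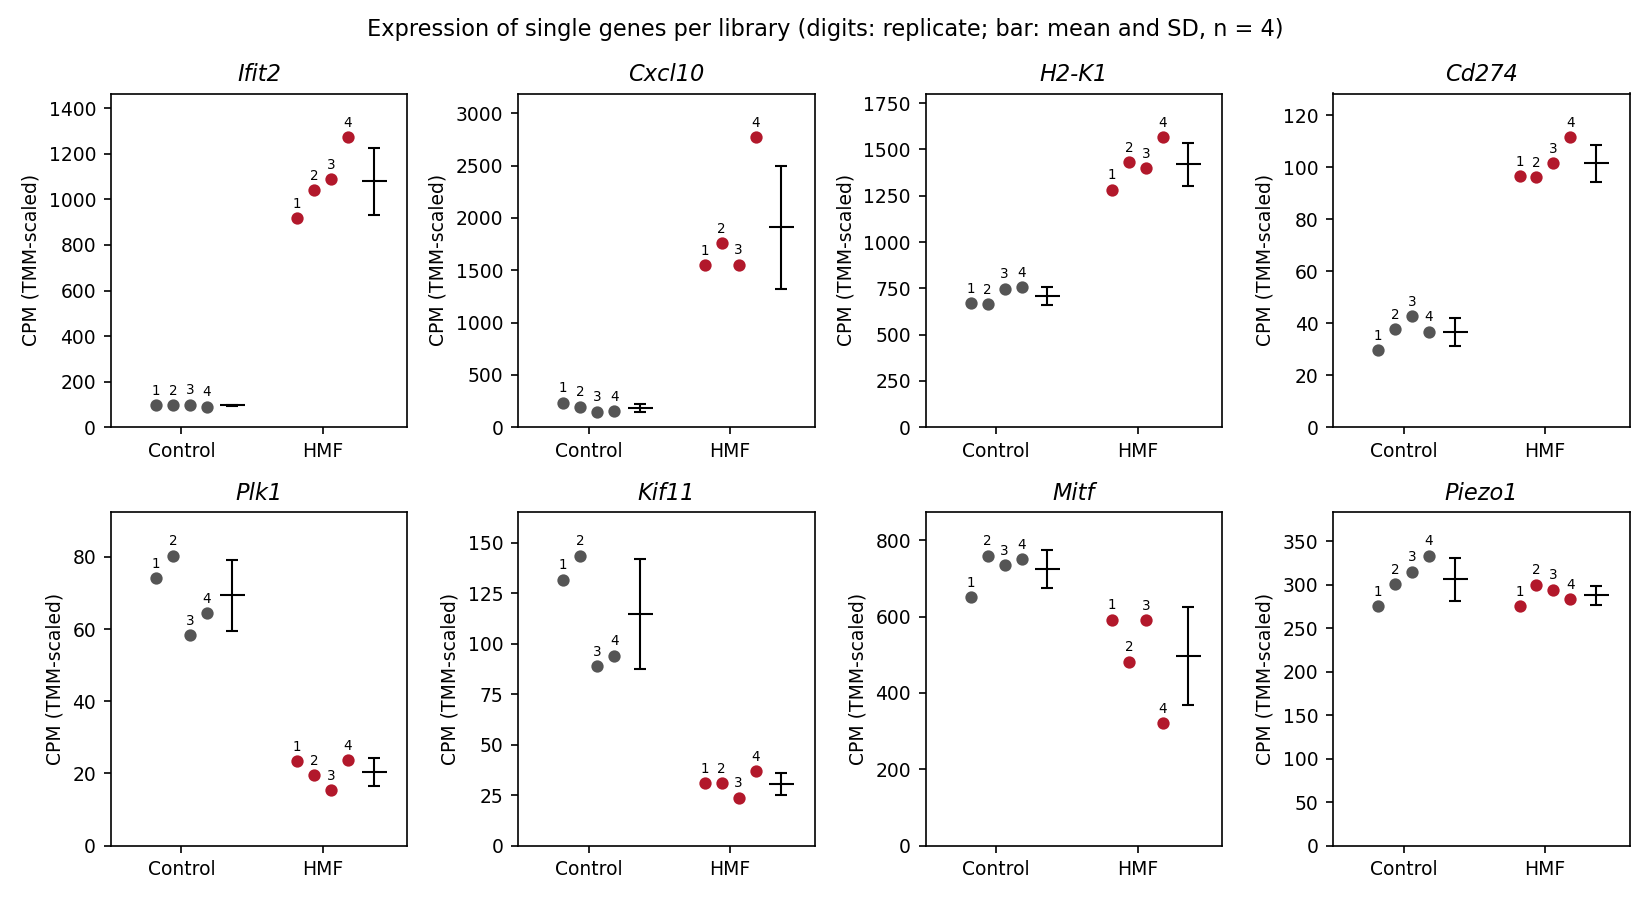
Points are TMM-scaled CPM of single genes in each library, with the replicate number above each point and the mean and SD (n = 4) beside them; vertical axes start at 0. Ifit2 went from a mean of 95.3 to 1080 CPM and Kif11 from 115 to 30.7 CPM, while Piezo1 had 306 CPM in Control and 288 CPM in HMF.

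Most tested genes of inflammatory cell death rose, and 11 of 22 apoptosis genes did. Of 12 tested pyroptosis and necroptosis genes 10 rose and 1 fell (10 and 1 adjusted over the list alone; median 0.83, camera adjusted p = 1.47e-12, 0.0256 with an estimated correlation). Besides Zbp1, the pore-forming gasdermin gene Gsdmd rose by 1.67 ± 0.11 (adjusted p = 1.25e-06) and Mlkl, which encodes the executor of necroptosis, by 1.38 ± 0.10 (adjusted p = 2.3e-06). Gsdme rose by 0.29 ± 0.09 (adjusted p = 0.0379), Gsdmc fell by 0.48 and Pycard (0.20) did not pass. The list was fixed with 19 genes. Casp1, Ripk3, Nlrp3, Nlrp1b, Nlrc4, Il1a and Il1b were below the count filter and were not tested. The apoptosis list had 11 rises and 1 fall among 22 tested genes (13 and 1 adjusted over the list alone; median 0.38, camera adjusted p = 9.44e-04, 0.0423 with an estimated correlation). Bid rose by 1.20 ± 0.11 and Cflar, which encodes an inhibitor of death receptor signalling, by 0.56 ± 0.08. Of 20 tested p53 targets 8 rose and 2 fell (10 and 3 adjusted over the list alone; median 0.29, camera adjusted p = 0.0348, adjusted p = 0.572 with an estimated correlation). Cdkn1a, which encodes the cell cycle inhibitor p21, rose by 0.87 ± 0.09 (adjusted p = 3.24e-05) and Plk2 by 1.503 ± 0.22. The death receptor gene Fas rose by 2.35 ± 0.37 at a low level, from 0.357 ± 0.215 to 1.88 ± 0.556 CPM (SD, n = 4). In contrast, Sesn1 fell by 0.50 and Ei24 by 0.20. The call of the p53 list was lost without Control 3 (adjusted p = 0.0589) and without Control 4 (0.0555).

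Both cell cycle lists were lower in HMF. All 24 tested genes of G2 and mitosis fell, each at least 2-fold (24 adjusted over the list alone). Their median fell by 1.54 on the log2 scale (camera adjusted p = 3.66e-38, but adjusted p = 0.0932 with an estimated correlation). Bub1b, a spindle checkpoint kinase gene, fell by 1.49 ± 0.11, Aurkb by 1.53 ± 0.12 and Plk1 by 1.75 ± 0.14 (adjusted p = 6.78e-06), the last from 69.3 ± 9.81 to 20.5 ± 3.94 CPM (SD, n = 4). Of 25 tested genes of S phase and DNA replication 22 fell and none rose (23 adjusted over the list alone). The median fell by 0.92 (camera adjusted p = 3.71e-14, but adjusted p = 0.275 with an estimated correlation). E2f1 and E2f2, which encode transcription factors of S phase entry, fell by 0.99 ± 0.07 and 1.21 ± 0.13, and Rrm1, a ribonucleotide reductase subunit gene, by 1.09 ± 0.13. Mcm6 (-0.26) and Ccne1 (-0.17) were among the 3 that did not pass.

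Cholesterol biosynthesis genes were lower too, with 20 falls and no rise among 23 tested (22 adjusted over the list alone). The median fell by 0.53 (camera adjusted p = 5.43e-12, but adjusted p = 0.155 with an estimated correlation). Fdft1, which encodes squalene synthase, fell by 0.81 ± 0.09 and the squalene epoxidase gene Sqle by 0.53 ± 0.05. Tm7sf2 (-0.28), Hsd17b7 (-0.26) and Sc5d (-0.18) did not pass. Of 18 tested pigmentation genes 10 fell and none rose (10 adjusted over the list alone). That median fell by 0.36 (camera adjusted p = 0.00893, but adjusted p = 0.545 with an estimated correlation). The mean log2 CPM of the pigmentation list lay close in Control 1 (8.62) and HMF 1 (8.59). In HMF 4 it was 8.03, against 8.44 to 8.59 in the other HMF libraries. The melanosome transporter genes Slc45a2 and Slc24a5 fell by 0.53 ± 0.13 and 0.35 ± 0.09, and Rab27a, which serves melanosome transport, by 0.81 ± 0.20. Mitf, the master regulator of melanocytes, fell by 0.55 ± 0.16 (adjusted p = 0.0285) and Tyr, the tyrosinase gene, by 0.65 ± 0.19 (adjusted p = 0.0283). The libraries of the groups overlapped for Tyr.

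**Figure D3:**
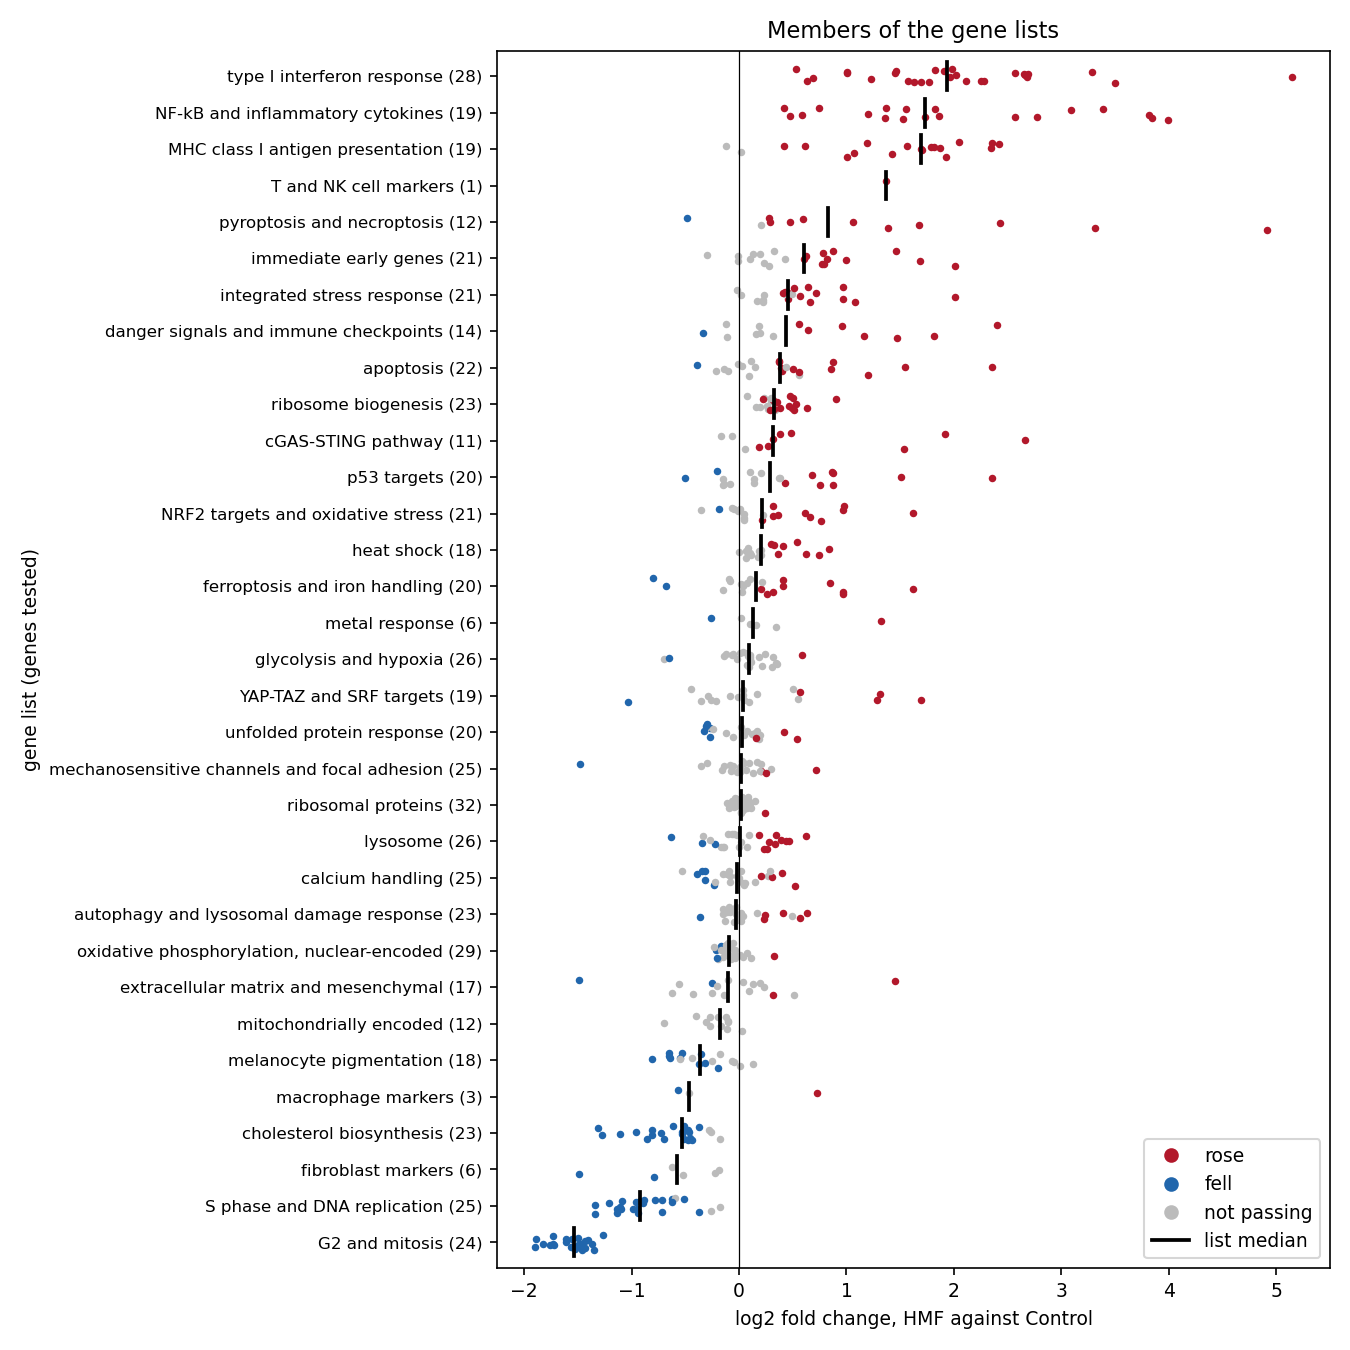
Each row is a gene list with the number of tested genes in brackets, each point the log2 fold change (HMF against Control) of a member, coloured by whether it rose, fell or did not pass, and each bar the list median. The medians ran from -1.54 for G2 and mitosis to 1.94 for the type I interferon response.

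Stress programmes were partly raised. In the integrated stress response list 13 of 21 tested genes rose and none fell (15 adjusted over the list alone; median 0.46, camera adjusted p = 2.03e-04, adjusted p = 0.572 with an estimated correlation). Besides Atf3, Ppp1r15a, which encodes a phosphatase subunit that restores translation, rose by 1.08 ± 0.13 and Nupr1 by 0.72 ± 0.14. The mean log2 CPM of the list overlapped between the groups, at 7.033 in Control 1 and 7.022 in HMF 1. Of 18 tested heat shock genes 8 rose and none fell (10 adjusted over the list alone; median 0.20, camera adjusted p = 0.00924, adjusted p = 0.572 with an estimated correlation), with Hsph1 at 0.54 ± 0.08, Dnajb4 at 0.62 ± 0.10 and Bag3 at 0.41 ± 0.07. Hspa1a was below the count filter, with 2, 1, 4 and 4 counts in Control and 0, 1, 0 and 5 in HMF. Its paralog Hspa1b, with which it may share reads, rose by 0.74 (adjusted p = 0.0462 by edgeR). Among 21 tested NRF2 targets 10 rose and 1, Sod1, fell by 0.19 (11 and 1 adjusted over the list alone; median 0.21, camera adjusted p = 0.015, adjusted p = 0.572 with an estimated correlation). The heme oxygenase gene Hmox1 rose by 1.62 ± 0.15, from 156 ± 22.2 to 480 ± 111 CPM (SD, n = 4; adjusted p = 1.99e-05), Osgin1 by 0.66 ± 0.09 and Srxn1 by 0.76 ± 0.14. The mean log2 CPM of the NRF2 list overlapped as well, at 6.78729 in Control 1 and 6.78725 in HMF 1. Ribosome biogenesis had 14 rises and no fall among 23 tested genes (16 adjusted over the list alone; median 0.32, camera adjusted p = 6.53e-04, adjusted p = 0.632 with an estimated correlation), among them Rrp12 (0.91 ± 0.16), Polr1a (0.38 ± 0.08) and Nop14 (0.47 ± 0.10). The mean log2 CPM of that list was 6.51 and 6.496 in Control 1 and Control 2, 6.18 and 6.22 in Control 3 and Control 4, and 6.56 to 6.98 in HMF.

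In the remaining stress lists the set test did not pass, although single members changed. Of 20 tested ferroptosis and iron genes 9 rose and 2 fell (9 and 3 adjusted over the list alone; median 0.15, camera adjusted p = 0.206). Gch1 rose by 0.84 ± 0.12, while the transferrin receptor gene Tfrc fell by 0.68 ± 0.06 and the iron exporter gene Slc40a1 by 0.80. Among 6 tested metal response genes the zinc exporter gene Slc30a1 rose by 1.32 ± 0.15 and the zinc importer gene Slc39a10 fell by 0.26 ± 0.07 (2 rises and 1 fall adjusted over the list alone; camera adjusted p = 0.311). Mt1 (0.34), Mtf1 (0.16), Slc39a14 (0.10) and Slc30a5 (0.02) did not pass over all genes. Of 20 tested genes of the unfolded protein response 3 rose and 5 fell (4 and 7 adjusted over the list alone; camera adjusted p = 0.967), with a median of 0.03, a mean of -0.00606 and a downward set test. Syvn1 rose by 0.54 ± 0.07, Dnajb9 by 0.42 ± 0.08 and Hyou1 by 0.16, while Sdf2l1 fell by 0.32 ± 0.08, Creld2 by 0.31, Pdia4 by 0.30, Sec24d by 0.27 and Hsp90b1 by 0.27.

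Lists tied to mechanical stimulation and to lysosomes did not move in a single direction as sets. By fry for changes in either direction, their unadjusted p ran from 2.16e-08 (lysosome) to 1.18e-05 (autophagy). That test does not compare the members with the other genes. Piezo1, which encodes a mechanosensitive ion channel, had a log2 fold change of -0.09 ± 0.07 (adjusted p = 0.382). Of 25 tested genes of mechanosensitive channels and focal adhesion 3 rose and 1 fell (1 and 1 adjusted over the list alone; median 0.02, mean -0.00988, set test downward, camera adjusted p = 0.967). The integrin gene Itga5 rose by 0.71 ± 0.09, Rock1 by 0.25 and the channel gene Trpv2 by 0.20 ± 0.07, and Lmnb1, a nuclear lamina gene, fell by 1.48 ± 0.13. Of 19 tested YAP-TAZ and SRF targets 4 rose and 1 fell (4 and 1 adjusted over the list alone; median 0.04, camera adjusted p = 0.209). The receptor kinase gene Axl rose by 1.69 ± 0.08, Tagln2 by 1.29 ± 0.16, Crim1 by 0.57 ± 0.11 and Ctgf (now Ccn2) by 1.32, while the myosin light chain gene Myl9 fell by 1.03. Calcium handling had 4 rises and 5 falls among 25 tested genes (5 and 6 adjusted over the list alone; median -0.02, camera adjusted p = 0.779). Camk2d rose by 0.52 ± 0.07, Itpr2 by 0.40, Nfatc3 by 0.31 and Ppp3ca by 0.20. Stim1 fell by 0.39 ± 0.07, Calm3 by 0.34, Capn2 by 0.31 ± 0.06 and Calm2 by 0.31.

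Of 26 tested lysosomal genes 10 rose and 3 fell (10 and 5 adjusted over the list alone; median 0.00755, camera adjusted p = 0.481). Scarb2 rose by 0.62 ± 0.06 and the protease gene Ctsb by 0.46 ± 0.06, while the lysosomal calcium channel gene Mcoln1 fell by 0.63 ± 0.06, Ctsa by 0.34 and Tpp1 by 0.22. Lamp1 had a log2 fold change of 0.01 ± 0.06 (adjusted p = 0.891). Of 23 tested genes of autophagy and the lysosomal damage response 5 rose and 1 fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.572). Here the median was -0.02, the mean 0.06 and the set test upward. Lgals8, which encodes a galectin that marks damaged endosomes, rose by 0.56 ± 0.06, the autophagy receptor gene Sqstm1 by 0.64 ± 0.09, Tfe3 by 0.41 ± 0.08, Gabarapl1 by 0.24 and Atg12 by 0.24, while Wipi1 fell by 0.36.

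Genes of energy metabolism, translation and matrix showed few changes. Nuclear-encoded oxidative phosphorylation had 1 rise, Cycs (0.33 ± 0.07), and 3 falls, among them Ndufb3 by 0.22 ± 0.06 and Sdhd by 0.20 ± 0.07, in 29 tested genes (1 rise and 0 falls adjusted over the list alone; median -0.10, camera adjusted p = 0.248). None of 12 tested mitochondrially encoded genes passed by edgeR, and 1 had an unadjusted p below 0.05 (none adjusted over the list alone; median -0.18, camera adjusted p = 0.384), and without HMF 4 this list passed with a median of -0.43 (adjusted p = 0.0434). Among 26 tested glycolysis and hypoxia genes P4ha1 rose by 0.59 ± 0.11 and Ndrg1 fell by 0.66 ± 0.11 (1 and 1 adjusted over the list alone; median 0.09, camera adjusted p = 0.795). Of 32 tested ribosomal protein genes 1 rose and none fell (0 adjusted over the list alone; median 0.02, camera adjusted p = 0.877). In the extracellular matrix list 2 of 17 tested genes rose, among them Mmp2 by 0.31 ± 0.08, and the collagen genes Col1a2 and Col5a1 fell by 1.49 ± 0.28 and 0.25 (2 and 2 adjusted over the list alone; median -0.10, camera adjusted p = 0.779).

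**Figure D4:**
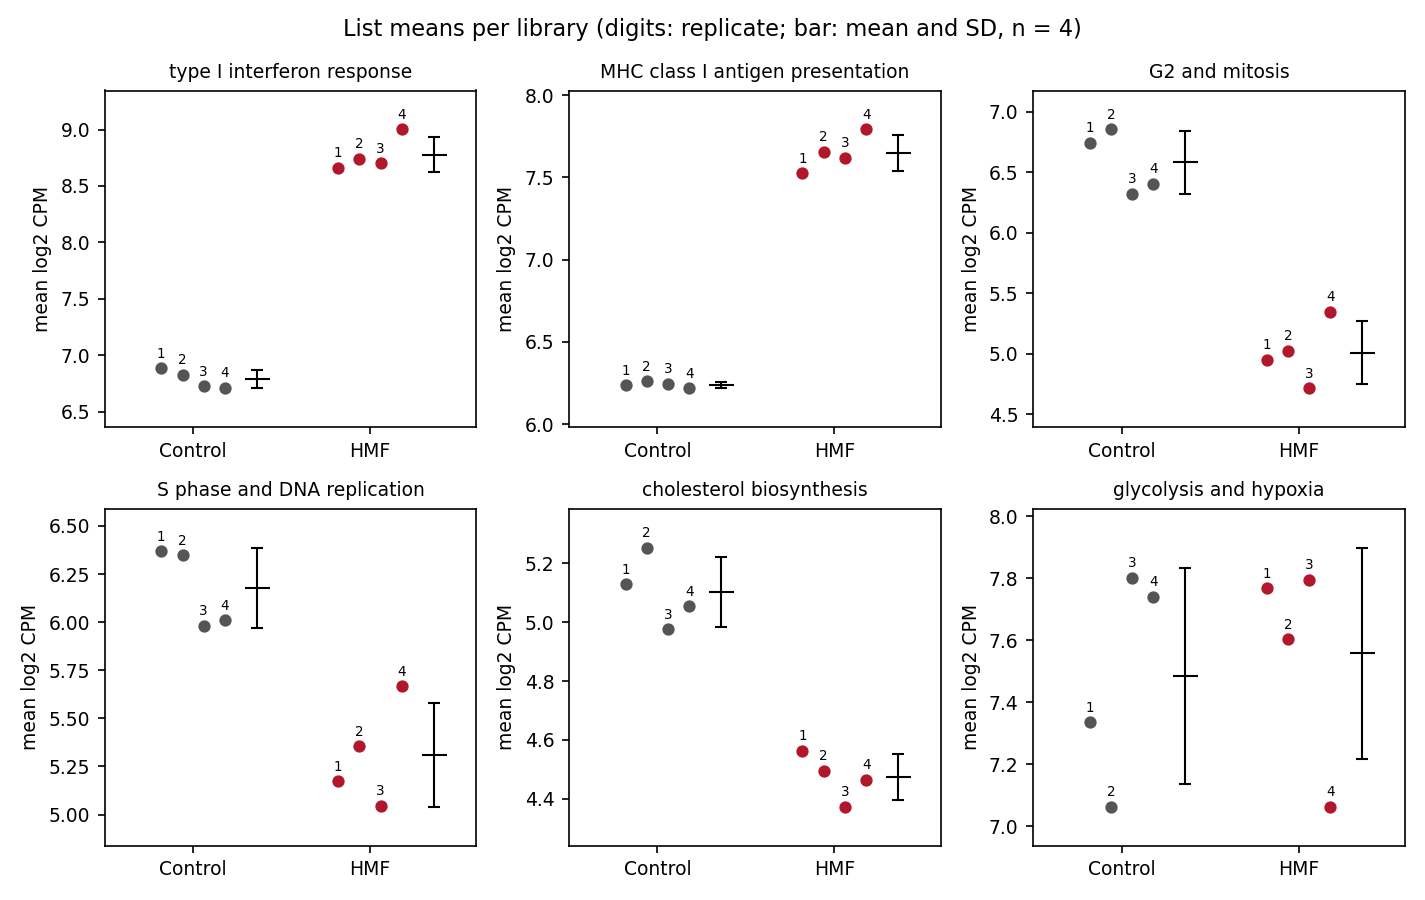
Points are the mean log2 CPM of the tested members of a list in each library, with the replicate number above each point and the group mean and SD (n = 4) beside them; vertical axes do not start at 0. The groups lay apart for the interferon, MHC class I, cell cycle and cholesterol lists, whereas the glycolysis and hypoxia means of Control 1, Control 2 and HMF 4 (7.34, 7.06 and 7.06) lay below those of the other 5 libraries.

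Markers of other cell types were counted beside the gene lists. Of 15 macrophage markers 3 passed the count filter, of which Cd68 rose by 0.72 ± 0.14, Fcer1g fell by 0.57 ± 0.17 and Lyz2 (-0.47) did not pass (1 and 1 adjusted over the list alone; camera adjusted p = 0.967). Beside the interferon and cytokine genes, the summed CPM of the macrophage markers was 14.8 ± 1.55 in Control and 18.8 ± 0.825 in HMF (SD, n = 4), and without Cd68 it was 6.49 ± 0.755 and 4.997 ± 0.235. Ptprc, the pan-leukocyte gene CD45, had 0 counts in Control and 2 in HMF. Among T and NK cell markers only Lck could be tested, and it rose by 1.37 ± 0.27, from 77 to 195 counts in all 4 libraries together. The summed CPM of the T and NK cell markers was 1.62 ± 0.397 and 3.49 ± 0.839, and that of the keratinocyte and epithelial markers, none of which could be tested, was 0.481 ± 0.168 and 0.776 ± 0.183 (SD, n = 4). The fibroblast markers summed to 353 ± 23.1 CPM in Control and 297 ± 17.5 CPM in HMF (SD, n = 4), mostly from Fbln1 with 19745 counts in Control and 16436 in HMF. Of 6 tested fibroblast markers Col1a2 and Pdgfrb fell by 1.49 ± 0.28 and 0.79 ± 0.12 and none rose (2 falls adjusted over the list alone). Their median fell by 0.57 (camera adjusted p = 0.0393, but adjusted p = 0.193 with an estimated correlation), and the call was lost without Control 1 (adjusted p = 0.0528) and without HMF 1 (0.0656).

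In all, 18 of 32 tested lists passed with the preset correlation, 13 upward and 5 downward, and 6 with an estimated correlation. Of the 35 splits of the 8 libraries into 4 and 4, 11 gave as many lists, the real split included, with up to 21. Apart from the real one, each of these kept 3 of the 4 libraries of each group together, so they still carried part of the group difference. Several calls near the threshold were lost when single libraries were left out. Gsdme lost its call without Control 2, 3 or 4 or HMF 2, 3 or 4 (adjusted p up to 0.103), and Mitf and Tyr without Control 2, 3 or 4 or HMF 2 (up to 0.0749 and 0.0752). The same held for Sdhd without Control 3 or 4 or any HMF library (up to 0.124), for Ndufb3 without Control 1 or 4 or HMF 1, 3 or 4 (up to 0.0831), for Trpv2 without Control 1, 2 or 3 or HMF 1, 2 or 3 (up to 0.106), for Fcer1g without Control 1, 2 or 3 or HMF 1 or 2 (up to 0.0896) and for Slc39a10 without Control 4 or HMF 2 (up to 0.0607). Trpv2 also lost its call with upper quartile scaling, Trpv2 and Gsdme with library sizes alone or on FPKM, and Ndufb3, Sdhd, Trpv2 and Gsdme without a count filter. Members of multigene families with similar sequences (Ifi203, Ifi204, Ifi209, Ifi213, Gbp10, Ifit3b, Serpina3f, H2-K1, Hspa1a and Hspa1b) may share reads with their paralogs. No source used here states whether counting used strand, so reads of antisense neighbours cannot be told apart. The members Pdia3, Irf3, Mavs, Cgas, Tmem173, Gsdmc, Pycard, Sesn1, Ei24, Mcm6, Ccne1, Tm7sf2, Hsd17b7, Sc5d, Hspa1b, Sod1, Slc40a1, Mt1, Mtf1, Slc39a14, Slc30a5, Hyou1, Creld2, Pdia4, Sec24d, Hsp90b1, Rock1, Ctgf, Myl9, Itpr2, Nfatc3, Ppp3ca, Calm2, Calm3, Ctsa, Tpp1, Gabarapl1, Atg12, Wipi1, Col5a1, Fbln1 and Lyz2 were chosen after their values were seen.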

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

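The tests of the glycolysis and hypoxia pattern against sequencing depth, and the use of its list mean as a covariate, were chosen after the result was seen. In 288 groups of 4 values, 18 had a library that stood apart from the other 3 by more than the 95% limit of Dixon's test, where chance gives about 1 in 20. Of these, 6 were in Control 1, 5 in Control 2, 6 in HMF 4 and 1 in HMF 3.

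In HMF 4 the total count was 19295358, against 14159514 to 14945878 in the other HMF libraries. Zbp1 stood at 196.7 CPM there against 138 to 143 in the others, Mlkl at 559.7 against 422 to 445 and Hmox1 at 645.4 against 412 to 431. The mean log2 CPM of HMF 4 was 7.65 for the lysosome list (7.78 to 7.80 in the others) and 6.04 for the autophagy list (6.15 in each of the others). Tfrc stood at 168.2 CPM in HMF 3 against 163 in each of the others. In Control 1, Sqstm1 stood at 1022 CPM against 902 to 918, Cdkn1a at 762.3 against 653 to 669, Srxn1 at 128.9 against 94.4 to 100.1, Atf3 at 36.6 against 24.6 to 25.2 and Csf1 at 241.6 against 223 to 225. The NRF2 list mean of Control 1 was 6.79 against 6.58 to 6.60. In Control 2, Tfe3 stood at 61.97 CPM against 77.3 to 77.6, Zfp36 at 8.67 against 12.5 to 13.2, Ndrg1 at 54.8 against 71.2 to 73.8, Fdft1 at 47.8 against 38.2 to 39.1 and Calr at 951.3 against 787 to 802.

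Control 1, Control 2 and HMF 4 were also the libraries with the lowest mean log2 CPM of the glycolysis and hypoxia list (7.34, 7.06 and 7.06, against 7.60 to 7.80 in the other 5), with a range of 0.738 over the 8 libraries. Sequencing depth is excluded as the whole source: the rank correlation of the list mean with the total count was -0.262 (Pearson r = -0.312, exact permutation p = 0.536 and 0.45, adjusted over 3 correlations 0.536 and 0.45, n = 8; r = 0.0633 without HMF 4 and Control 4), and the deepest and the shallowest library, HMF 4 and Control 2, both stood at 7.06. Mitochondrial reads were too few to take the share, at 2.47% to 4.45% of the counts of a library. Removing the mitochondrially encoded genes could therefore hardly change the range, which was 0.755 without them. The list mean still correlated with the mean log2 CPM of those genes at r = -0.900 (exact permutation p = 0.00216, adjusted 0.00647, n = 8). Without HMF 3 and HMF 4 r was -0.915, and over all libraries rho was -0.929 (exact permutation p = 0.00223, adjusted 0.0067). A difference in RNA or library preparation stays open and is a candidate source: the list mean correlated with the share of 18S ribosomal RNA at r = -0.848 (exact permutation p = 0.0113, adjusted 0.0169, n = 8), with r = -0.789 without Control 1 and Control 2 and rho = -0.667 (p = 0.0831, adjusted 0.125). Within their groups, Control 1, Control 2 and HMF 4 also had the highest S phase list means. These were 6.37 and 6.35 in Control 1 and Control 2, against 5.98 and 6.01 in Control 3 and Control 4. In HMF 4 the mean was 5.67, against 5.05 to 5.35 in the other HMF libraries. No biological explanation was tested or set aside, since no group of the design separates Control 1, Control 2 and HMF 4 from the rest.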

How the results depend on the processing

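The covariate for the glycolysis and hypoxia list was chosen after seeing the data, and the other alternatives before. The count of changed genes was 2288 at an adjusted p below 0.01, by the stricter threshold itself. At least 2-fold changes numbered 412 by limma on FPKM with a pseudocount of 1, which shrinks low genes, and 330 by glmTreat (268 rises and 62 falls), which tests against 2-fold. With an estimated correlation 6 lists passed, all upward, and the cause was not tested. Under the other scalings, filters and tools the count of changed genes was 3913 to 4258 and that of at least 2-fold changes 736 to 1023. Under the scalings and filters, the only ones of these where lists were run, 18 lists passed (20 by fry). Over the same scalings, filters and tools the share of rises ran from 41.3% (limma on FPKM, pseudocount of 1) to 52.1% (RLE size factors). Leaving out each library gave 3140 to 3804 changed genes, 826 to 924 of at least 2-fold and 17 to 19 lists. Of the 4030 calls 2708 were kept in all 8 of these fits, and none changed sign in any. The covariate gave 5910 genes, among them 4029 of the 4030, with 880 of at least 2-fold and 18 lists. The replicate numbers did not pair the samples: correlations of same-numbered libraries were -0.26, -0.08, 0.22 and -0.32, and not every sample correlated best with its own number. With the replicate number as a block 2785 genes were called and 18 lists passed. It ended the calls of Sdf2l1 (adjusted p = 0.0525), Tyr (0.0574), Mmp2 (0.0597), Slc39a10 (0.0701), Sdhd (0.0969), Fcer1g (0.0975), Ndufb3 (0.106), Gsdme (0.113) and Trpv2 (0.133). Over 109 named genes no called direction changed, and in 68 of 2071 comparisons a call was lost. Over 32 lists 16 of 544 comparisons lost a call, 12 of them with an estimated correlation, and 3 gained one (ferroptosis and metal response by fry, mitochondrially encoded genes without HMF 4). In the simulation, which changed far fewer genes than the 4030 called here, many 1.5-fold changes were missed (58.5% recovered). With fewer changed genes the adjusted threshold is stricter, so this share does not carry over to these data.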

Other observations

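The tests of pathways below and the tests of macrophage RNA, of the genes of interferon beta and gamma and of Cdkn1a were chosen after the result was seen. In the pathway annotation deposited with the table, 52 of 239 pathways passed camera with the preset correlation, 40 upward and 12 downward, and 11 with an estimated correlation. The DNA replication pathway had 25 falls and no rise among 35 genes (median -0.63, camera adjusted p = 3.06e-10, 0.602 with an estimated correlation). Whether the falls in the DNA repair pathways below were separate from the fall of replication and S phase genes was not tested. Of the DNA repair pathways non-homologous end-joining did not pass, with 6 falls and 1 rise among 12 genes (adjusted p = 0.203). In the Fanconi anemia pathway, which repairs crosslinks between DNA strands, 22 of 51 genes fell and 1 rose (adjusted p = 9.41e-07, 0.471 with an estimated correlation), with Fancd2 at -1.18 ± 0.16 (SE). Homologous recombination had 16 falls and 1 rise among 27 genes (adjusted p = 3.01e-06, 0.586 with an estimated correlation), with Blm at -0.93 ± 0.13. Mismatch repair had 14 falls and no rise among 22 genes (adjusted p = 4.09e-06, 0.547 with an estimated correlation), with Exo1 at -1.19 ± 0.21. In base excision repair 16 of 33 genes fell and 1 rose (adjusted p = 0.00882, 0.725 with an estimated correlation), and in nucleotide excision repair 15 of 43 fell and 1 rose (median -0.06, adjusted p = 0.0255, 0.977 with an estimated correlation).

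Proteasome genes showed 13 rises and no fall among 41 (adjusted p = 1.03e-04, 0.8286 with an estimated correlation). The immunoproteasome subunit genes Psmb9, Psmb10 and Psmb8 rose by 2.35 ± 0.10, 2.42 ± 0.11 and 1.69 ± 0.10. RIG-I-like receptor signaling, which senses RNA in the cytosol, had 26 rises and no fall among 48 genes (adjusted p = 1.37e-11, 0.0526 with an estimated correlation), with Ifih1 at 1.77 ± 0.10. The endosomal RNA sensor gene Tlr3 rose by 1.70 ± 0.07. Nfkbia rose by 1.83 ± 0.13, Tnfaip3 by 1.73 ± 0.20, Usp18 by 1.97 ± 0.08 and Socs1 by 1.602 ± 0.18, whereas Socs3 stood at 0.03 ± 0.18 (adjusted p = 0.927). The long noncoding RNA Neat1 fell by 0.85 ± 0.13. These genes were chosen after their values were seen.

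Of 35 splits of the 8 libraries, 1, the real one, gave as many as 4030 changed genes (highest other 0). The same held for the 843 at least 2-fold changes (1 of 35, highest other 0). This argues against a chance split of these libraries, at the smallest share that 35 splits allow. A chance difference between cultures was not tested, as the libraries of a group may share a culture. In the other splits, where the group difference adds to the spread, up to 2116 genes had an unadjusted p below 0.05 by edgeR, against 5734 in the real one. Chance was not excluded for the number of lists, which 11 of 35 splits reached (real 18, highest other 21). Each of the other splits with at least 18 lists kept 3 of the 4 libraries of each group together.

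Interferon and antigen presentation genes rose in HMF. RNA from macrophages is argued against: with Cd68 included, the summed CPM of the 15 macrophage markers rose by 3.97 (2.57 SD of the Control libraries), which is 0.0215% of the rise of 18452.6 CPM in the type I interferon and MHC class I lists, and Lyz2 had 90 counts in Control and 61 in HMF. Interferon gamma made by the cells is argued against by 0 counts of Ifng in the 4 HMF libraries (63163760 counts in all; 0 allows up to 3) at this time of harvest. A candidate explanation is that the cells transcribed interferon beta: Ifnb1 rose by 2.65 ± 0.42 (adjusted p = 8.45e-04; 49 counts in Control and 309 in HMF, 168 of them in HMF 4), and by 2.10 without HMF 4 (adjusted p = 6.77e-05; range without each library 2.10 to 2.83). Ifnb1 is itself a member of the type I interferon list, in which all tested members rose. Its rise is thus part of the pattern and no separate support for this explanation. Whether the micromotors, the field or their combination set off the interferon response was not tested.

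Genes of the G2 and mitosis list and of the S phase list fell in HMF, and in the wider cell cycle pathway of the annotation 52 of 118 genes fell and 15 rose (median -0.20, adjusted p = 2.17e-05, 0.737 with an estimated correlation). A trend of the fold change with GC content, gene length and abundance is excluded as the whole cause, since the median of the G2 and mitosis list was -1.57 after its removal and -1.54 before. Glycolysis and hypoxia genes differed between libraries but hardly between groups. Their list mean was 7.49 ± 0.349 in Control and 7.56 ± 0.340 in HMF (SD, n = 4). As a covariate that mean could hardly move the median of the G2 and mitosis list, which was -1.50 with it, so that fit excludes nothing. Fewer dividing cells through p53 and Cdkn1a may account for the fall, as Cdkn1a rose by 0.87 (adjusted p = 3.24e-05), while the p53 list lost its call with an estimated correlation (adjusted p = 0.572). Direct effects of the treatment on division, as opposed to the interferon response, were not tested.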
